A study of Drosophila melanogaster with 81 samples.

How the data were processed

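CUT&Tag libraries were made by the authors from whole Drosophila melanogaster embryos of 2 genotypes, w1118 and homozygous Df(2L)HisC, collected from 30-minute egg lays at 25°C and aged to 3.5 to 4 h, 4.5 to 5 h or 5.5 to 6 h after egg laying. Mutant embryos were picked by eYFP expression, so the HisC embryos also carry a GAL4 and a UAS-eYFP transgene that w1118 lacks. Genotype, background, transgenes and selection were thus changed together. The series holds 81 libraries in 36 groups; 59 libraries in 26 groups are behind the peak lists used here. The other 22 libraries, in 10 groups (H3K4me3 of embryos with the CyO balancer, histone H1, RNA polymerase II and its ser2 form), were not analysed here.

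The deposited lists hold, for each group, peak positions: a chromosome, a start counted from 0 and an end in bp, with no height, score or p-value. Lists of H3K4me3 and H3K27ac are of the narrow type and the others of the broad type, so the marks differ in how peaks were called. Lists of a mark are of the same type in both genotypes, and whether they were called alike in other respects is unknown. Per the labels, reads were handled with Trim Galore 0.6.6, cutadapt 1.17, Bowtie2 2.3.4.2, SAMtools 1.9 and deepTools 3.3.1 on dm6. The peak caller, its threshold and the way replicates were combined are not given in the sources used here. Names of the lists state that blacklisted regions were taken out, and the name of the HisC list of H3K4me3 at 3.5 to 4 h also states an exclusion whose meaning is not given. Chromosome names, order of start and end and overlaps within a list were checked, and 0 overlapping peaks were found within a list.

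Depth per library is unknown, and a list with more reads behind it can hold more and wider peaks. Each list stands for a group of 2 or 3 libraries and is here called pooled, although how the libraries were combined is unknown. No spread between replicates could therefore be computed, and no value of a single gene or list was tested between the genotypes. Clopper-Pearson 95% intervals of shares of peaks cover counting error only.

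The gene table for dm6 (release 6 of the genome) has 13946 protein-coding genes among 17872 genes, with start and end but neither strand nor transcripts. Promoter windows around transcription starts, as planned, were therefore replaced by windows around both ends of a gene, and exons and introns were not separated. For H3K4me3, H3K27ac, H2AK9ac and H2BK16ac a gene counted as marked when a peak overlapped the 500 bp on each side of either end, and its value was the bp covered within 2000 bp of either end. For H3K27me3 and H3K36me3 a gene counted as marked when at least 50% of its body was covered, and its value was the share of the body covered. Locations were within 500 bp of a gene end, elsewhere in a gene, or between genes.

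Lists of the genotypes were compared at the same time and mark by the number of peaks, covered length, the width of peaks that met exactly 1 peak of the other list, the Jaccard index (shared over united bp) and the share of peaks overlapped by at least 1 bp. Each of 5 measures over the marks was tested with an exact two-sided sign-flip permutation test over the 6 marks, each mark being the mean over 4.5 to 5 h and 5.5 to 6 h, with Benjamini-Hochberg adjustment over the 5 tests. The smallest p it can give is 0.03125, and the p speaks for these marks and not for replicate embryos. A single mark was called higher or lower only if at least 1.5-fold in 1 direction at both times. Overlaps are set beside 1000 circular shifts of a list along each chromosome.

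The 18 gene lists were the Hox genes, Polycomb target transcription factors, segmentation genes, mesoderm genes, neuroectoderm and neuroblast genes, dorsal ectoderm and amnioserosa genes, endoderm genes, early cellularization genes, maternal germline genes, cell cycle genes, apoptosis and DNA damage genes, histone variant and chaperone genes, histone modifying enzyme genes, ribosomal protein genes, proteasome genes, chemoreceptor genes, cuticle protein genes and the replication-dependent histone genes, which had no peak in any list. All but 1 of the listed symbols matched the gene table. A list's mean difference, HisC minus w1118 over both times, was ranked among 10000 random lists of the same size. These were matched on coverage in 10 quantile bins and not on gene length. A list stood apart under percentile 2.5 or over 97.5. Some genes belong to more than 1 list.

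Named genes were, per mark, the 10 with the largest differences in covered bp in each direction, among genes with the same sign at both times and a symbol other than a CG or CR number, ranked by the smaller of the differences at the 2 times. To these were added up to 4 genes per list, every Hox gene for H3K27me3, and stg, twi and sna. The text gives a part of them, and Lamp1 and CG8665 were added after their values were seen.

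Alternatives were peaks of at least 500 bp, equal numbers of the widest peaks per list of a mark, peaks closer than 1000 bp merged, the 5 large arms alone, each mark left out in turn, each time alone, overlap of at least 50% of a peak, windows of 1000 bp, and 25% of the gene body. After seeing the data, whole gene spans extended by 500 bp, equal covered length per list of a mark, and H3K27me3 peaks merged over 5000 bp were added. The overlap and gene list measures were tested on simulated data: lists made to keep 70% of peaks gave back the share drawn, and lists of 20 random genes stood apart in 5% of trials. For H3K4me3, H3K27ac, H2AK9ac and H2BK16ac, lists with 600 bp added to each of their genes were found in 94% of trials or more. Lists with 300 bp added, nearer to many of the differences reported, were found in 52% to 88%. No such trial was run for H3K27me3 and H3K36me3, so how well their list differences can be found is unknown.

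Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.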

Results

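CUT&Tag, in which an antibody against a chromatin mark directs a transposase to cut and tag the DNA around it, was used to map 6 histone modifications in whole Drosophila melanogaster embryos. Wild-type w1118 embryos were compared with embryos homozygous for Df(2L)HisC, here called HisC, a deficiency that removes the cluster of replication-dependent histone genes. H3K27me3 is the mark of Polycomb repression, H3K36me3 covers transcribed gene bodies, H3K4me3 and H3K27ac lie at active promoters and enhancers, and H2AK9ac and H2BK16ac are acetylations of the other core histones. All 6 marks were mapped at 4.5 to 5 h and 5.5 to 6 h after egg laying, and H3K4me3 also at 3.5 to 4 h. The comparisons ask whether the marks keep their places when embryos go through DNA replication without newly made histones.

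The 26 groups analysed here held 59 libraries, with 2 or 3 libraries per group, and each group had 1 pooled list of peak positions. The lists held 4588 to 13436 peaks and covered 5.47 to 13.7 Mb, or 3.98% to 9.97% of the genome. Sequencing depth and peak height are unknown, so a value of 0 means that no peak was called, not that the mark was absent. With 1 pooled list per group there was no replicate check for any gene, and gene values are therefore reported as higher or lower in one list than in the other. Percentiles place a gene list among random lists matched on coverage and describe these peak lists, without testing the genotypes. Pairs of values are given for 4.5 to 5 h and then for 5.5 to 6 h, with positions in dm6.

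At the histone gene cluster itself (2L 21416953–21541681, 111 genes), none of the 26 lists had a peak in either genotype, so the deleted DNA gave no check of the labels. Around it, no HisC list had a peak in the 153 kb from 21400836 to 21554171, where the w1118 lists held 4 separate peaks. Of the 69 stretches of at least 30 kb that had at least 3 w1118 peaks and no HisC peak, 4 were at least that long, this one included. In the reverse case, of 61 such stretches without a w1118 peak, 6 were at least that long. The length of the gap cannot decide whether it goes with the deletion, since the 125 kb of the cluster within it had no w1118 peak either. Genes beside the cluster, named here after their values were seen, went both ways. Lamp1 (2L 21573389–21577103) had 964 and 1184 bp of H3K4me3 around its ends in w1118 at 4.5 to 5 h and 5.5 to 6 h, and 404 and 373 bp in HisC, while CG8665 (2L 21371227–21377995), on the other side, had 0 bp in w1118 and 375 and 270 bp in HisC. For H3K27ac, Lamp1 was at 1168 and 1387 bp against 558 and 382 bp, and CG8665 at 360 and 0 bp against 1167 and 1338 bp. The eye pigment gene w (X 2790599–2796466), part of which is deleted in w1118, ranked top among the genes with more H3K4me3 in HisC, at 0 and 333 bp in w1118 and 2016 and 2366 bp in HisC.

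H3K27me3 was lower over Hox genes and other Polycomb targets in HisC. The 8 Hox genes, which set segment identity and are the classic Polycomb targets, had on average 62.4% of their gene bodies covered in w1118 and 38.1% in HisC at 4.5 to 5 h, with all 8 lower in HisC. At 5.5 to 6 h the means were 67.4% and 43.7%, with 7 of 8 lower. Abd-B (3R 16927212–16972236) was covered to 76.9% in w1118 and 37.9% in HisC at the earlier time, and Antp (3R 6896253–6999228) to 52.5% and 24.8%. Dfd was the exception, at 70.2% and 70.9% at 5.5 to 6 h. As a list the Hox genes stood at percentile 4.16 among matched random lists, which did not set them apart.

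**Figure D1:**
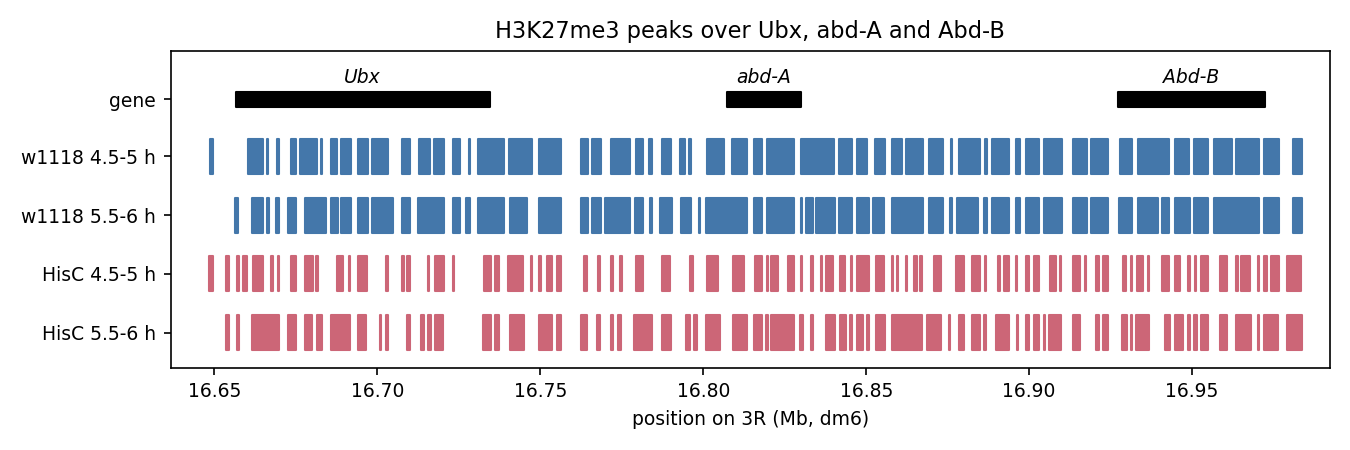
H3K27me3 peaks in both genotypes at 4.5 to 5 h and 5.5 to 6 h along the bithorax region (3R 16636623–16992236, with position in the dm6 assembly on the horizontal axis, 1 line of bars per list and genes drawn above). Peaks covered 205.7 kb in w1118 and 113.4 kb in HisC at the earlier time, and 216.8 and 153.2 kb at the later time, in shorter and more numerous pieces in HisC.

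Across the bithorax region, which holds Ubx, abd-A and Abd-B, the number of H3K27me3 peaks was 55 in w1118 and 83 in HisC at 4.5 to 5 h, and the longest peak was 10.4 kb and 4.42 kb. Other transcription factors under Polycomb control showed the same direction: 38 of 59 had less H3K27me3 in HisC at both times and 8 had more, and their mean coverage was 64.04% in w1118 and 51.0% in HisC (percentile 0.01). Lim1, nub, svp and inv had the largest differences in bp of this list, with inv (2R 11474465–11509695) at 54.6% in w1118 and 30.9% in HisC at 4.5 to 5 h. Genes of the neuroectoderm and neuroblasts were lower too, at 53.9% and 35.4% (percentile 0.19), among them the achaete-scute complex gene ase (X 460747–463176), at 66.7% and 74.3% in w1118 and 0 in both HisC lists. The zinc-finger gene nerfin-1 (3L 909112–912319) was fully covered in w1118, at 100% at both times, and at 43.5% and 49.3% in HisC.

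The genes of apoptosis and DNA damage had a mean H3K27me3 coverage of 16.1% in w1118 and 1.06% in HisC (percentile 0.02). Of the 11 genes, the 4 that differed at both times were all lower: the cell death activators skl (3L 18438561–18439942), hid and rpr, and the stress-response transcription factor Xrp1 (3R 18914968–18926989). The skl gene body was at 100% in both w1118 lists and 0 in both HisC lists, rpr was at 26.9% and 24.8% in w1118, hid at 11.5% and 13.2%, and Xrp1 at 36.2% and 34.7%, with 0 for each in HisC. As hid, rpr and skl lie in 1 region of 3L, from 18167745 to 18439942, they are not independent of each other.

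In bp, the RNA-binding protein gene bru3 (3L 13521907–13803400) ranked first among the named genes with less H3K27me3 in HisC, by the smaller of the differences at the 2 times. It had 63675 and 61305 bp covered in w1118 and 20416 and 25818 bp in HisC. At CadN (2L 17647053–17778340), which encodes N-cadherin, coverage was 33187 and 42415 bp in w1118 and 4139 and 5379 bp in HisC, and at the adhesion gene Fas3 (2L 18320102–18393441) it was 27277 and 34535 bp against 1418 and 3240 bp. The Hox cofactor gene hth (3R 10507561–10639568) had 40611 and 35497 bp in w1118 and 9502 and 9495 bp in HisC. In all, 217 genes had at least 50% of the gene body covered in w1118 at both times and in HisC at neither, and 363 genes had the reverse (755 when 25% of the body was enough).

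H3K27me3 was also present in HisC at genes with little or none in w1118. The glucose transporter gene Glut1 (3L 914074–993788) had 0 bp in w1118 at both times and 12958 and 15326 bp in HisC, and the mucin gene Mur2B (X 1523554–1668788) had 835 and 0 bp in w1118 and 17314 and 14608 bp in HisC. Also on this side were the potassium channel genes Shab and SLO2, the immunoglobulin-domain genes dpr12 and dpr6, the neuropeptide receptor gene RYa-R and the myoblast fusion gene kirre. Shab (3L 2895017–2959579) was at 0 bp in w1118 and at 9104 and 8577 bp in HisC. These genes were ranked in bp, which favours long genes. Of the gene body, 16.3% and 19.2% was covered in HisC for Glut1, 14.1% and 13.3% for Shab and 11.9% and 10.1% for Mur2B. For SLO2 the shares were 8.48% and 11.4%, and for dpr6 6.66% and 13.2%. For kirre they were 3.39% and 2.45%, below the 6.65% and 7.96% of the genome covered in these lists. Chemoreceptor genes, which serve smell and taste in larvae and adults, had a mean coverage of 8.505% in w1118 and 21.8% in HisC (percentile 100), and 14 and 13 of 179 were at least 50% covered in w1118 against 33 and 42 in HisC. Or59c (2R 23472300–23473753) was uncovered in w1118 and at 100% in HisC at both times.

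Cuticle protein genes stood at 9.32% in w1118 and 21.7% in HisC (percentile 99.17), a difference that no longer stood apart when the lists of the mark were reduced to the same number of widest peaks (percentile 77.4). Of its 98 members, Cpr is a cytochrome P450 reductase gene that the name rule took in. Ribosomal protein genes had no H3K27me3 in w1118 and 3.89% in HisC (percentile 99.94, and 96 with equal numbers of peaks), with RpL14 (3L 8601006–8602392) at 56.9% and 52.0% in HisC. Chemoreceptor and cuticle genes lie in runs of neighbours, and of 300 lists made of 20 neighbouring genes 24.7% stood apart for H3K27me3, against 2.67% of lists of random genes.

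The HisC lists of H3K27me3 held more peaks, with a smaller median width. They had 8320 and 8313 peaks against 4605 and 4588 in w1118, 1.81-fold more at each time, and the median width was 778.5 and 924 bp against 1634 and 1571.5 bp. Peaks of 5 kb and more numbered 522 and 529 in w1118 and 50 and 130 in HisC. Covered length was 10.9 and 10.9 Mb in w1118 and 9.13 and 10.9 Mb in HisC.

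H3K36me3 was lower in HisC over many genes: 984 genes were at least 50% covered in w1118 at both times and in HisC at neither, against 181 genes with the reverse (366 when 25% of the body was enough). SMC5 (3L 21569176–21573523), a subunit of a chromosome maintenance complex, had 98.7% and 100% of its body covered in w1118 and 0 in HisC. The retinoblastoma gene Rbf (X 797090–801479) had 3926 and 2880 bp in w1118 and 325 and 842 bp in HisC, and the ribosomal protein gene RpS29 (3R 9778042–9779528) had 1487 bp in both w1118 lists and 0 in both HisC lists. Genes of histone variants and histone chaperones had a mean coverage of 64.5% in w1118 and 33.1% in HisC, with 14 of 18 lower at both times and none higher (percentile 1.64, and 2.84 with equal numbers of peaks). Among them, Caf1-105 (2R 10466001–10468540), a subunit of the chaperone that loads histones at replication forks, had 2470 and 2240 bp in w1118 and 691 and 1278 bp in HisC.

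On chromosome 4, H3K36me3 covered 138 and 205 kb in w1118 and 59.1 and 54.1 kb in HisC. The receptor tyrosine kinase gene Eph (4 610684–622470) had 5545 and 5866 bp in w1118 and 0 in HisC, Ank was at 4312 and 6724 bp in w1118 and 0 in HisC, and CaMKII at 5042 and 5672 bp against 263 and 736 bp. The log2 ratio of covered length on this chromosome was −1.22 and −1.92, and on the 5 large arms it lay between −0.11 and 0.08 at 4.5 to 5 h and between −0.51 and −0.30 at 5.5 to 6 h. H3K27me3 was lower on chromosome 4 as well, at 135 and 144 kb in w1118 and 55.4 and 63.1 kb in HisC, with log2 ratios of −1.29 and −1.20 against −0.43 to −0.05 and −0.22 to 0.22 on the large arms.

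Within 3 Mb of the centromeres lay 2.66% of the H3K36me3 length in w1118 at both times and 5.69% and 5.00% in HisC. This was not particular to H3K36me3, as every other mark except H3K27me3 also had a larger share there in HisC at both times. Myo81F (3R 567076–2532932) had 1435 and 897 bp of H3K36me3 in w1118 and 63921 and 53949 bp in HisC. DIP-lambda (2R 326768–705848) had 0 bp in w1118 and 43811 and 32529 bp in HisC, and Pzl and lovit were likewise at 0 in w1118. These genes are long. In HisC, 3.25% and 2.74% of Myo81F was covered, 3.81% and 2.39% of Pzl and 11.6% and 8.58% of DIP-lambda, against 8.19% and 7.69% of the genome. The muscle genes Msp300 (2L 5100877–5207002) and Mhc (2L 16766566–16788766), outside the 3 Mb next to the centromeres, had 0 bp in w1118. In HisC they had 13232 and 13179 bp, and 5298 and 5310 bp. Cuticle protein genes had 1.11% of their bodies covered in w1118 and 5.06% in HisC (percentile 100), apoptosis genes 16.3% and 24.9% (percentile 97.53), and chemoreceptor genes 4.84% and 5.49% (percentile 98.17). The chemoreceptor result ended with equal numbers of peaks (percentile 97.12, where the difference was −0.115).

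H3K27ac was the mark with the most genes marked in w1118 alone: 1845 genes had a peak at an end in w1118 at both times and in HisC at neither (1220 with windows of 1000 bp), and 308 had the reverse. Within 500 bp of a gene end lay 40.5% and 42.1% of the H3K27ac length in w1118 and 19.4% at both times in HisC. The genome itself had 14.7% there, so the HisC lists as a whole were little concentrated at gene ends. Whether the differences at single genes named for this mark go beyond that was not tested. Germline genes supplied to the egg had a mean of 1149 bp in w1118 and 488 bp in HisC, with 9 of 10 lower (percentile 0.91); gcl (2R 8724258–8728999), needed to form germ cells, was at 2124 and 2386 bp against 0 and 347 bp, and the Piwi-pathway genes aub and piwi were at 0 in HisC at 4.5 to 5 h. Genes of the dorsal ectoderm and amnioserosa had 1048 and 423 bp, with 15 of 18 lower (percentile 0.2). In that list the T-box genes Doc1 (3L 9041375–9045042) and Doc2 had 1148 and 1799 bp, and 1212 and 1648 bp, in w1118 and 0 in HisC, and the GATA factor gene pnr had 891 and 948 bp in w1118 and 0 in HisC.

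The mitotic cyclin gene CycB (2R 22803521–22806948) had 1660 and 2086 bp of H3K27ac in w1118 and 0 in HisC, and its kinase partner Cdk1 had 1570 and 2159 bp against 510 and 287 bp. Cell cycle genes marked at an end numbered 30 and 35 of 38 in w1118 and 17 and 16 in HisC, but as a list they stood at percentile 37.6 in H3K27ac. The RNA processing genes Trf4-1 and Hrb27C, the tumour suppressor gene l(3)mbt (3R 27266326–27273273, 2606 and 2715 bp against 0 and 176 bp) and the adducin gene hts were among the 10 genes with the largest differences in favour of w1118. PlexA, an axon guidance receptor gene on chromosome 4, had 2737 and 2662 bp in w1118 and 0 in HisC. Polycomb target transcription factors had 816 bp in w1118 and 519 bp in HisC (percentile 2.24), a difference that did not stand apart with windows of 1000 bp (percentile 47.4), with equal numbers of peaks (4.25) or over whole gene spans (3.50).

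H3K27ac was higher in HisC at Ir40a (2L 22189526–22214376), a receptor gene close to the centromere, with 0 bp in w1118 and 2814 and 3116 bp in HisC. Cdc23 (2L 20459342–20461729), which encodes a subunit of the anaphase-promoting complex, had 0 and 373 bp in w1118 and 3253 and 3011 bp in HisC. The amino acid transporter gene mnd and the dopamine receptor gene Dop1R1 were at 0 in w1118 and at 1974 and 2121 bp, and 2006 and 1881 bp, in HisC.

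H3K4me3 had the highest overlap between the genotypes by the Jaccard index and by the share of w1118 peaks, with 5622 genes marked at an end in all 4 later lists, 273 in w1118 alone at both times and 321 in HisC alone. With equal numbers of peaks the latter were 689 and 166. Of the w1118 peaks, 81.6% (95% Clopper-Pearson interval 80.5% to 82.6%) overlapped a HisC peak at 4.5 to 5 h and 86.3% (85.3% to 87.1%) at 5.5 to 6 h, but of the more numerous HisC peaks only 53.8% and 56.4% overlapped a w1118 peak. Neuroectoderm and neuroblast genes were lower, with a mean of 1269 bp in w1118 and 939 bp in HisC, 9 of 18 lower at both times and 4 higher (percentile 0). Of these, nerfin-1 had 1592 and 1536 bp in w1118 and 0 in HisC, ase had 1486 and 1934 bp against 0 and 322 bp, and l(1)sc had 767 and 1089 bp against 0 and 276 bp. Measured over whole gene spans, the list's difference was 47.7 bp in favour of HisC and did not stand apart (percentile 6.43).

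Segmentation genes had 1345 bp of H3K4me3 in w1118 and 1199 bp in HisC (percentile 0.2, and 15.7 with windows of 1000 bp). Within the list, btd (X 9694186–9697558) and slp2 had 1277 and 1745 bp in w1118 and 0 in HisC at 4.5 to 5 h, and the pair-rule gene eve was the other way, at 807 and 537 bp in w1118 and 1691 and 2252 bp in HisC. Spc25, a kinetochore gene, Rab40 and the nuclear export gene sbr were among the genes with the most bp missing in HisC, with Spc25 (3R 12961745–12963249) at 1955 and 1491 bp in w1118 and 0 in HisC. Higher in HisC were the polyubiquitin gene Ubi-p63E (3L 3899259–3903184), at 0 bp in w1118 and 2310 and 1882 bp in HisC, the eye pigment gene bw, the transcription factor gene gsb-n and the condensin gene Cap-G. Chemoreceptor genes had 143 bp in w1118 and 228 bp in HisC (percentile 97.98).

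The H3K4me3 lists of 3.5 to 4 h differed most in number, with 6475 peaks in w1118 and 12294 in HisC, and medians of 874 and 464 bp in width. These lists were not made alike, as the w1118 list pools 3 libraries and the HisC list 2, and the name of the latter states an exclusion whose meaning is not given. At that time 73.3% of w1118 peaks overlapped a HisC peak and 45.1% of HisC peaks a w1118 peak, and 55.8% of the covered length lay within 500 bp of a gene end in w1118 against 28.9% in HisC. Later, the HisC lists held 8613 and 8991 peaks against 5336 and 5728 in w1118, 1.61-fold and 1.57-fold more.

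Ribosomal protein genes carried more H2AK9ac and more H2BK16ac in HisC. For H2AK9ac their mean was 451 bp in w1118 and 774 bp in HisC, 21 and 21 of 92 were marked at an end in w1118 and 27 and 52 in HisC, and the percentile was 100. For H2BK16ac the mean was 263 and 681 bp, with 7 and 16 marked in w1118 and 30 and 34 in HisC (percentile 100). Of the length of these marks, 13.8% to 17.9% lay within 500 bp of a gene end in each list, against 14.7% of the genome. Their Jaccard index with H3K4me3 at 4.5 to 5 h was 0.076 in w1118 and 0.199 in HisC for H2AK9ac. For H2BK16ac it was 0.050 and 0.177. Whether the higher coverage of ribosomal protein genes goes with a background common to the HisC libraries was not tested. RpS27A (2L 10408352–10410456), a fusion of ubiquitin and a ribosomal protein, had 0 bp of H2AK9ac in w1118 and 2221 and 2156 bp in HisC, and RpL19 (2R 24967877–24969547) had 0 bp of H2BK16ac in w1118 and 1917 and 2278 bp in HisC. Histone modifying enzyme genes had 465 bp of H2BK16ac in w1118 and 853 bp in HisC (percentile 99, and 96.5 with windows of 1000 bp), with the Polycomb group gene Su(z)12 at 239 and 1333 bp against 1957 and 2248 bp.

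Among single genes, H2AK9ac was higher in HisC at mi, at the heterochromatin protein gene Su(var)3-7 (3R 13264364–13270038; 1103 and 755 bp against 3565 and 3833 bp) and at Clamp, whose product binds GA repeats at the histone cluster and on the X. It was lower at the glycosidase gene Oga (3R 21219077–21222843; 3308 and 4947 bp against 0 and 1506 bp), at the midline glia gene wrapper and at the neuronal gene elav (X 509235–523226; 2120 and 2103 bp against 0 and 334 bp). H2BK16ac was higher at the kinesin gene Klp59D, at the ATP synthase gene ATPsyngamma and at the actin nucleation gene Arp3. It was lower at Mef2 (2R 9913496–9958858), the muscle differentiation factor gene, at 2625 and 3503 bp in w1118 and 527 and 729 bp in HisC, and at the Notch pathway gene Tom, at 2309 and 1936 bp against 0.

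Dorsal ectoderm genes had 934 bp of H2BK16ac in w1118 and 697 bp in HisC (percentile 1.95), cuticle protein genes 661 and 584 bp (percentile 1.07), and chemoreceptor genes 724 and 701 bp (percentile 2.42). None of these 3 stood apart with windows of 1000 bp, at percentiles 3.20, 2.73 and 7.36, or over whole gene spans, at 13.3, 8.90 and 17.8.

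**Figure D2:**
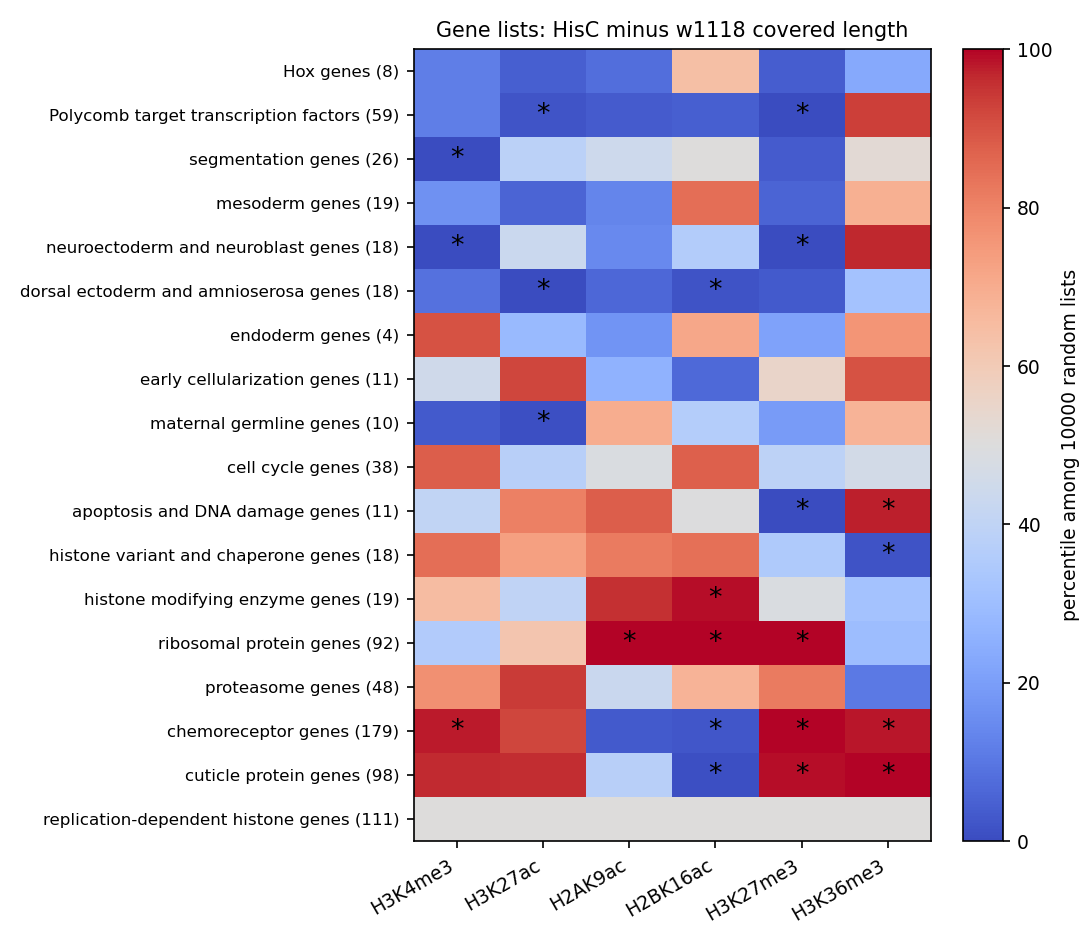
Percentile of each gene list's mean difference in coverage, HisC minus w1118, among 10000 random lists of the same size matched on coverage, for 6 marks; low percentiles mean less coverage in HisC than in matched lists and an asterisk marks lists that stood apart. Ribosomal protein genes are at 100 for H2AK9ac and H2BK16ac, and Polycomb target transcription factors at 0.01 for H3K27me3.

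Of 108 pairs of a gene list and a mark, 6 of them of the histone cluster genes, which had no peak, 22 stood apart. Over all marks, lists of 20 random genes stood apart in 5% of trials and lists of 20 neighbouring genes in 19.7%; how far neighbouring genes within the 18 lists account for the 22 was not tested. Mesoderm genes did not stand apart in any mark, with percentiles from 5.47 to 84.7, nor did endoderm genes (17.4 to 89.96), early cellularization genes (6.67 to 92.1), cell cycle genes (37.6 to 87.7) or proteasome genes (10.9 to 94.0). Among the genes fixed in advance, the cell cycle phosphatase gene stg (3R 29251826–29255800) had 1680 and 1794 bp of H3K4me3 in w1118 and 1362 and 1453 bp in HisC, but more H3K27ac in HisC, at 930 and 1222 bp against 1773 and 1526 bp, and more H2AK9ac, at 0 and 257 bp against 1157 and 1054 bp. The mesoderm gene twi had 1787 and 1874 bp of H3K4me3 against 1913 and 2391 bp, and 11190 and 5594 bp of H3K27me3 against 11327 and 13077 bp. For sna, H3K4me3 was at 1475 and 1167 bp against 750 and 1307 bp, and H2AK9ac at 0 and 243 bp against 537 and 1604 bp. The HisC genotype also carries a transgene in which a twi promoter drives GAL4, which adds copies of that sequence.

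**Figure D3:**
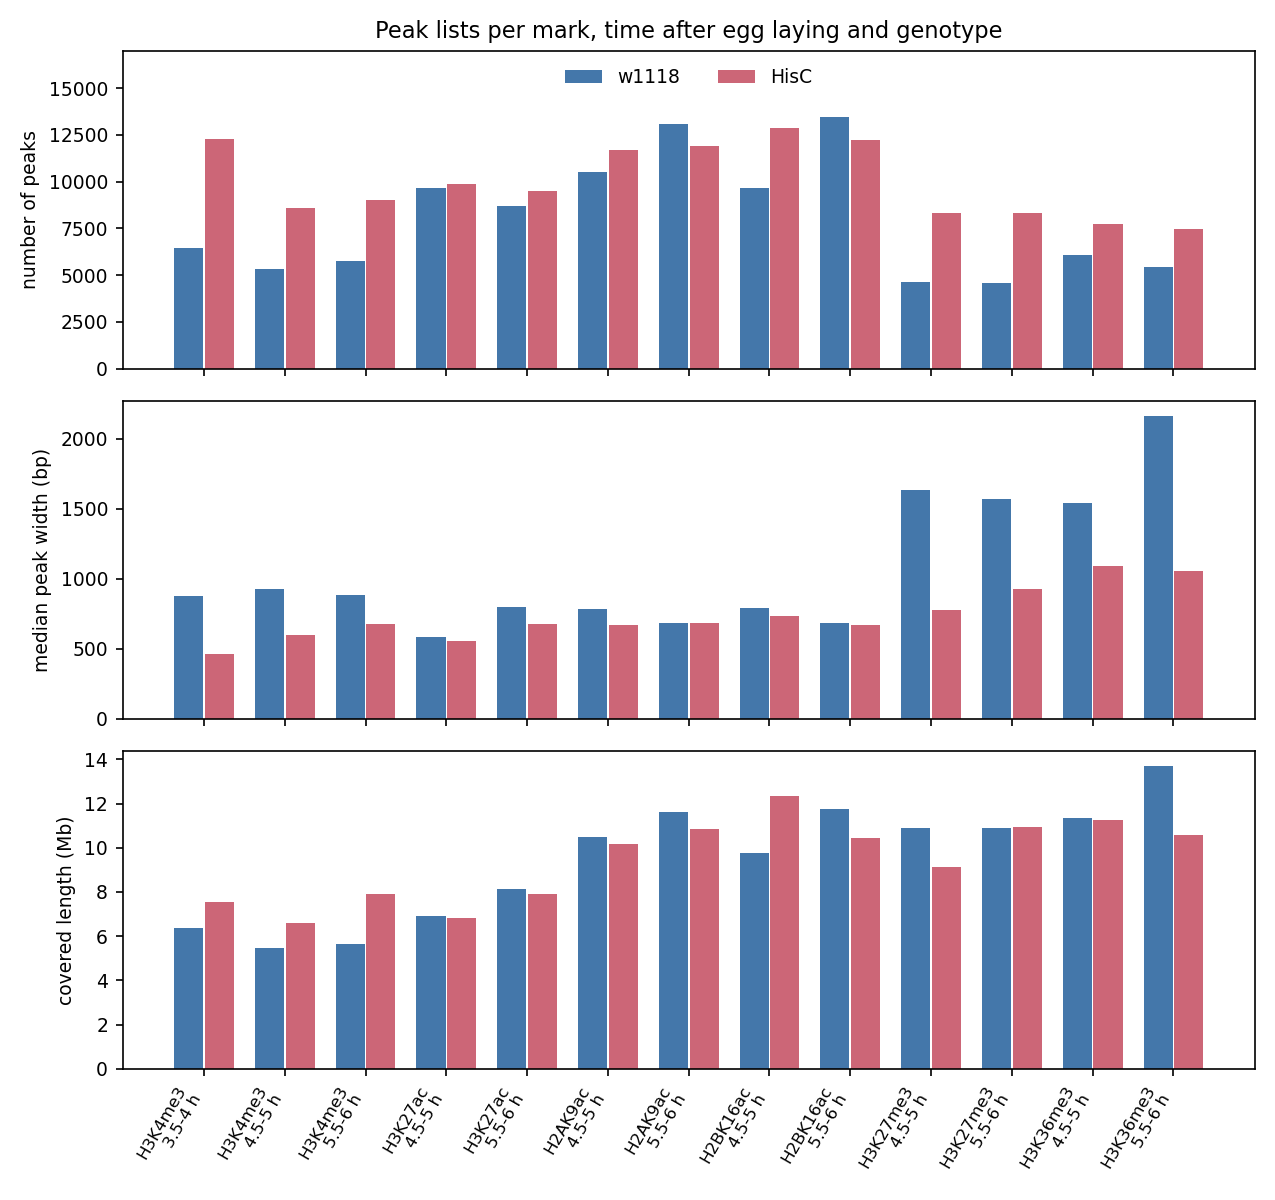
Number of peaks, median peak width in bp and covered length in Mb of each list, for w1118 and HisC at each time and mark (bars start at 0). The number of peaks of H3K27me3 was 4605 in w1118 and 8320 in HisC at 4.5 to 5 h, while its covered length was 10.9 and 9.13 Mb.

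The log2 ratio of peak number, HisC over w1118, was above 0 for each of the 6 marks as the mean of both times, but at 5.5 to 6 h it was below 0 for H2AK9ac (−0.138) and H2BK16ac (−0.136). The mean log2 ratio was 0.36 (SD 0.35, n = 6 marks), from 0.0071 for H2AK9ac to 0.86 for H3K27me3, with H3K4me3 at 0.67, H3K36me3 at 0.40, H2BK16ac at 0.14 and H3K27ac at 0.08. An exact two-sided sign-flip permutation test over the 6 marks gave p = 0.03125, the smallest it allows, and 0.078 after Benjamini-Hochberg adjustment over the 5 such tests. At 5.5 to 6 h alone the mean was 0.30, with exact p = 0.219, and without peaks under 500 bp it was 0.18, with exact p = 0.188. By the 1.5-fold rule set for a single mark, only H3K4me3 and H3K27me3 had more peaks in HisC at both times, and no mark met the rule in covered length or width.

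The log2 ratio of covered length was 0.38 for H3K4me3, 0.09 for H2BK16ac, −0.03 for H3K27ac, −0.07 for H2AK9ac, −0.12 for H3K27me3 and −0.19 for H3K36me3 as the mean of both times. Its mean over the marks was 0.0066 (SD 0.20, exact p = 0.969). The mean changed sign without H3K4me3, to −0.067, without H2BK16ac, to −0.0093, and under 3 other settings. For peaks that met exactly 1 peak of the other genotype, the log2 ratio of widths was below 0 for 5 of 6 marks, with H2BK16ac the exception, and its mean was −0.16 (SD 0.15, exact p = 0.0625, adjusted 0.104). The change of covered length between the later times differed between the genotypes by −0.08 (SD 0.31, exact p = 0.531, adjusted 0.664).

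**Figure D4:**
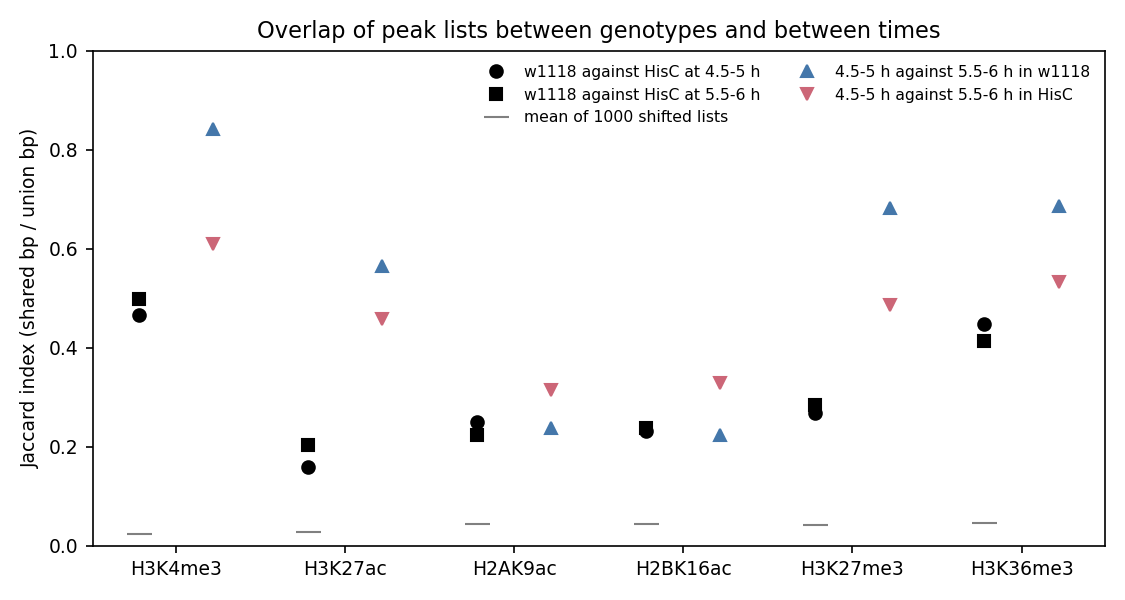
Jaccard index (shared over united covered length) of peak lists between genotypes at 1 time and between 4.5 to 5 h and 5.5 to 6 h within a genotype, per mark, with the mean of 1000 circular shifts. For H3K27ac the index between genotypes was 0.159 and 0.203, and between times 0.566 in w1118 and 0.457 in HisC.

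For H3K27ac, H3K27me3, H3K4me3 and H3K36me3, the genotype separated the lists more than 1 hour of development did. The index between genotypes was 0.159 and 0.203 for H3K27ac, 0.268 and 0.284 for H3K27me3, 0.466 and 0.499 for H3K4me3 and 0.448 and 0.413 for H3K36me3. Between the later times it was 0.566, 0.682, 0.842 and 0.686 for these marks in w1118 and 0.457, 0.486, 0.609 and 0.532 in HisC, which is nearer to the values between genotypes. H2AK9ac and H2BK16ac overlapped little in either direction, with 0.2499 and 0.224, and 0.232 and 0.238, between genotypes and 0.238 and 0.223 between times in w1118 and 0.315 and 0.329 in HisC. Against the w1118 value alone, H2BK16ac lists overlapped slightly more between genotypes than between times. The index between genotypes minus that between times was below 0 for 6 of 6 marks, with a mean of −0.19 (SD 0.13, exact sign-flip permutation p = 0.03125, the smallest possible, adjusted 0.078). Shifted lists gave means of 0.023 to 0.047 between genotypes.

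As shares of peaks, 39.2% (38.2% to 40.2%) and 48.6% of w1118 H3K27ac peaks overlapped a HisC peak, 62.4% (61.0% to 63.8%) and 63.8% for H3K27me3, and 76.2% (75.1% to 77.3%) and 75.6% for H3K36me3. For H2AK9ac the shares were 57.2% and 48.5%, and for H2BK16ac 60.7% and 50.6%. Of the HisC peaks, those overlapping a w1118 peak were 39.3% and 47.0% for H3K27ac, 43.2% and 41.7% for H3K27me3, 63.7% and 64.4% for H3K36me3, 52.5% and 53.5% for H2AK9ac and 46.6% and 56.1% for H2BK16ac. When at least 50% of a w1118 peak had to be overlapped, the share averaged over both times was 26.8% for H3K27ac, 34.5% for H2AK9ac and 38.3% for H3K27me3.

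**Figure D5:**
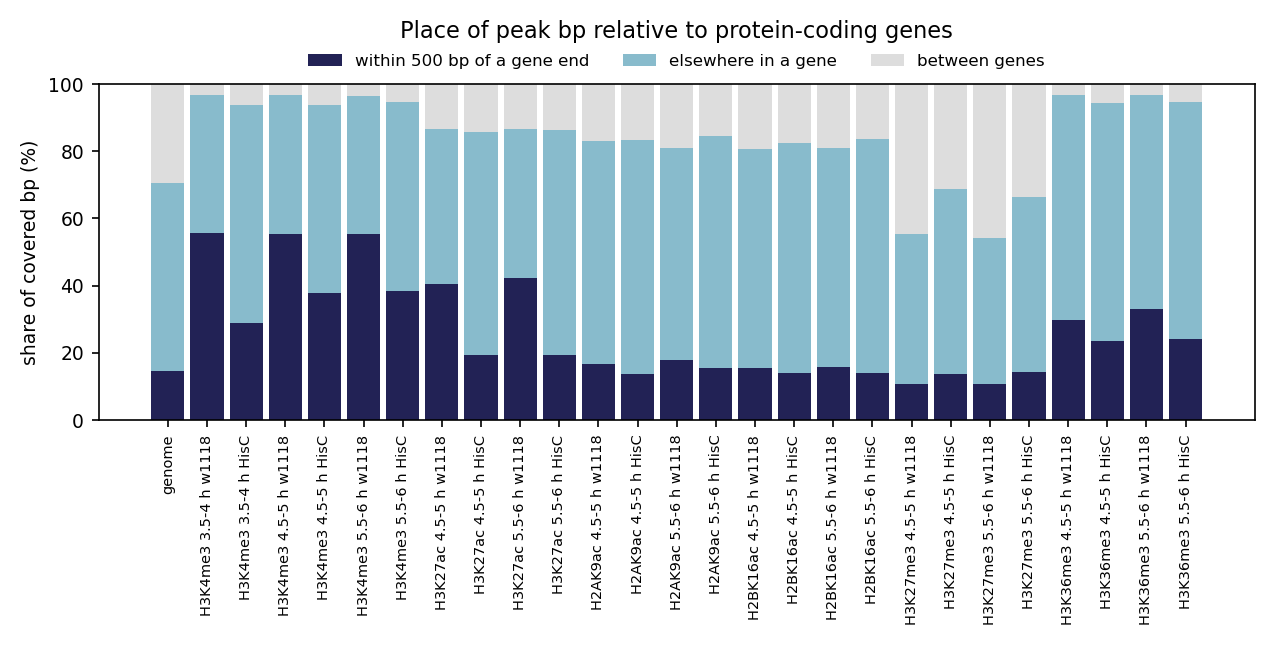
Share of covered length, in percent, within 500 bp of a gene end, elsewhere in genes and between genes, for each list and for the genome (14.7%, 55.7% and 29.6%). The share at gene ends for H3K27ac was 40.5% and 42.1% in w1118 and 19.4% at both times in HisC.

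In the HisC lists, H3K4me3 and H3K27ac had less of their length at gene ends and more inside genes than in the w1118 lists. At gene ends H3K4me3 had 55.3% and 55.4% of its covered length in w1118 and 37.8% and 38.6% in HisC, and H3K27ac 40.5% and 42.1% in w1118 and 19.4% at both times in HisC. For H3K27me3 the regions between genes held 44.6% and 45.7% in w1118 and 31.2% and 33.8% in HisC. The share inside genes was higher in HisC for 6 of 6 marks, by a mean of 9.85 points (SD 6.89, exact sign-flip permutation p = 0.03125, adjusted 0.094 over 3 places), a test chosen after the shares were seen. Gene ends gave a mean of −7.92 points with exact p = 0.125.

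H3K27me3 overlapped H3K4me3 and H3K36me3 more in HisC than in w1118. H3K4me3 covered 3.67% and 3.92% of the H3K27me3 length in w1118, 0.905 and 0.937 times the mean of shifted lists, and 12.7% and 10.1% in HisC, 2.57 and 1.73 times that mean. H3K36me3 covered 6.48% and 6.33% of it in w1118, 0.765 and 0.624 times the shifted mean, and 16.6% and 12.3% in HisC, 1.98 and 1.55 times. The acetylations overlapped H3K27me3 in both genotypes: H2AK9ac at 2.51 and 1.88 times the shifted mean in w1118 and 4.32 and 2.81 times in HisC, and H2BK16ac at 2.28 and 2.00 against 4.15 and 3.41. For H3K27ac the ratios were 1.79 and 1.81 in w1118 and 2.26 and 1.76 in HisC, so the direction differed between the times. These ratios are values for the 4 lists behind them, with no test between the genotypes.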

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

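All comparisons in this part were looked at only after the values at each time were seen, and with 1 pooled list per group none of these differences between the times was tested. Each concerns a log2 ratio of HisC over w1118 that lay on one side of 0 at 4.5 to 5 h and on the other at 5.5 to 6 h.

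For H2BK16ac the peak number ratio was 0.41 at 4.5 to 5 h and −0.14 at 5.5 to 6 h, a difference of −0.55. Its covered length ratio was 0.34 and −0.17, a difference of −0.51, and its ratio of widths of peaks met by exactly 1 peak was 0.07 and −0.05, a difference of −0.12. The H2BK16ac lists held 9668 and 13436 peaks in w1118 and 12856 and 12229 in HisC. For H2AK9ac the peak number ratio was 0.15 and −0.14, a difference of −0.29. Its lists pooled 3 libraries in w1118 and 2 in HisC at the earlier time and 2 and 3 at the later time, so at each time the list from fewer libraries held more peaks. The covered length ratio of H3K27me3 was −0.25 and 0.0037, a difference of 0.26. The width ratio of H3K4me3 was −0.12 and 0.02, a difference of 0.14.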

How the results depend on the processing

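Tests in this part that were chosen only after the result was seen are those with equal covered length, whole gene spans and peaks merged over 5000 bp; all other alternatives, the gene lists and the rule for named genes were set before the data were examined. Of 481 alternative values for 113 results, 401 were labelled unchanged, 29 kept the direction only, 43 moved and 8 reversed. Of the 401, 8 were values of a single mark that changed sign under the size limit. Values of a single mark, shares and gene counts were labelled by how far they moved, so the 401 do not count calls that held. With a mark left out, the exact sign-flip permutation test cannot pass the threshold for p. Its labels there were partly set by construction, and the tally does not measure how robust the results are. No paired analysis was possible because each list pools its replicates, and for the same reason a replicate block and leaving out each replicate were not run. The cause of the changes below was not tested unless stated, and depth, which is unknown, limits every count.

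Covered length, with a mean log2 ratio near 0, reversed to −0.059 with peaks of at least 500 bp, −0.11 with equal numbers of peaks and −0.034 at 5.5 to 6 h alone; leaving out each mark gave −0.067 to 0.047, below 0 without H3K4me3 or H2BK16ac. Peak number weakened to 0.18 with peaks of at least 500 bp, 0.33 with peaks merged and 0.30 at 5.5 to 6 h alone. Leaving out each mark gave 0.26 to 0.43 for peak number and −0.22 to −0.16 for genotype against time overlap, in both with an exact p of 0.0625, the smallest that 5 marks allow. Equal numbers of peaks make the peak number ratio 0 by construction and give no value for it.

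The share of w1118 peaks overlapped, as the mean of both later times, was 81.5% for H3K4me3, 40.5% for H3K27ac, 47.7% for H2AK9ac, 50.1% for H2BK16ac, 59.0% for H3K27me3 and 74.7% for H3K36me3 with peaks of at least 500 bp. Equal numbers of peaks gave 70.4% for H3K4me3, 42.3% for H3K27ac, 51.7% for H2BK16ac, 46.2% for H3K27me3 and 68.6% for H3K36me3, and merging gave 87.4% for H3K4me3 and 46.5% for H3K27ac. With at least 50% of the peak overlapped, a stricter rule by construction, the shares were 76.7%, 26.8%, 34.5%, 36.3%, 38.3% and 54.4% in the order of marks given first.

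Genes marked at both times in w1118 alone were, for H3K4me3, 689 with equal numbers of peaks, 165 with windows of 1000 bp and 170 over gene spans, and for H3K27ac 1220 and 1222 with the latter 2. In HisC alone they were 166 with equal numbers and 587 over gene spans for H3K4me3, and, with 25% of the body, 755 for H3K27me3 and 366 for H3K36me3.

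Gene list differences that no longer stood apart with windows of 1000 bp were −112.8 bp for segmentation genes in H3K4me3, −232 bp for Polycomb targets in H3K27ac, and in H2BK16ac −33.8 bp for chemoreceptor, −72.1 bp for cuticle, −187 bp for dorsal ectoderm and 184 bp for histone modifying enzyme genes. Over gene spans they were −391 bp for Polycomb targets in H3K27ac, and in H2BK16ac −40.2 bp for cuticle and −188 bp for dorsal ectoderm genes, and they reversed to 47.7 bp for neuroectoderm genes in H3K4me3 and to 4.08 bp for chemoreceptor genes in H2BK16ac. With equal numbers of peaks they were −288 bp for Polycomb targets in H3K27ac, −36.3 bp for chemoreceptor genes in H2BK16ac, 5.01 points for cuticle and 2.20 points for ribosomal protein genes in H3K27me3, and −32.4 points for histone chaperone genes in H3K36me3, where chemoreceptor genes reversed to −0.115 points.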

Other observations

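Tests of called pieces, chance assignment, a common background and shorter coverage on all chromosomes were chosen only after the result was seen. Those of chance calls and of chromosome 4 copies had their outcomes written down beforehand, the latter without the margin for counting error used below. The test of covered length uses a setting, equal covered length, that was added after seeing the data, and only its expected outcome was written down before it was run.

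H3K27ac had more of its length near the centromeres and on the Y chromosome in HisC. Within 3 Mb of the centromeres, 10.9% of the genome, lay 4.45% and 3.65% of the H3K27ac length in w1118 and 12.3% and 10.8% in HisC, and 5.44% and 8.33% of the H2AK9ac length in w1118 and 9.66% and 10.8% in HisC. H3K27me3 was at 3.71% and 3.86% in w1118 and 4.19% and 3.13% in HisC. On the Y chromosome H3K27ac covered 12.9 and 3.16 kb in w1118 and 46.4 and 69.0 kb in HisC, and H3K4me3 11.6 and 13.1 kb against 40.7 and 32.02 kb. The other acetylations differed little there at 4.5 to 5 h, with H2AK9ac at 66.5 and 35.9 kb in w1118 and 71.7 and 83.7 kb in HisC, and H2BK16ac at 76.4 and 36.7 kb against 75.8 and 61.9 kb. The X chromosome, 17.1% of the genome, held 8.26% and 13.7% of H2AK9ac peaks in w1118 and 9.57% and 11.3% in HisC.

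At 3L 3894999–3903184, which holds Gr63a, Lamtor4, Ccz1 and the polyubiquitin gene Ubi-p63E, the marks went opposite ways. Ccz1 had 0 bp of H3K4me3 in both w1118 lists and 1838 and 2777 bp in HisC, and 1802 and 2687 bp of H2BK16ac in w1118 and 0 and 323 bp in HisC.

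The HisC lists of H3K27me3 held more and narrower peaks. Calling wide w1118 domains in pieces does not account for the number, as no more than 44.4% of HisC peaks lay on w1118 peaks merged over 5000 bp, a setting chosen after seeing the data. Chance calls near the threshold do not account for all of it: of the HisC peaks without a w1118 peak, at least 64.1% overlapped the HisC list of the other time, against 27.8% in the highest of 1000 shifts. This comparison cannot exclude such calls among the peaks that were not found again. Nor can it tell the mark from weak background that recurs in both HisC lists. For the loss of wide peaks, calling in pieces remains open in part, since wide w1118 peaks were met by at least 1.896 HisC peaks on average and by 1.37 of the w1118 list of the other time. Splitting that kept their whole extent is not enough, as HisC peaks covered 40.8% and 47.5% of the length of these wide peaks and the w1118 list of the other time 87.3% and 85.9%; a difference in depth or in the mark itself was not tested.

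Lists of different marks overlapped each other more in HisC for 15 of 15 pairs of marks at 4.5 to 5 h (mean Jaccard index 0.116 in w1118, 0.206 in HisC) and 13 of 15 at 5.5 to 6 h (0.135 and 0.200), where H3K27ac with H3K4me3 (0.385 and 0.339) and with H3K27me3 (0.067 and 0.063) went the other way. Exchanging the genotypes of each mark gave a difference as large in 2 of 64 ways at each time (exact p = 0.03125), which is the smallest p that 6 marks allow and is not adjusted for the choice of the test after the pattern was seen, so the test decides nothing about chance assignment of the lists, which stays open. Over the 6 marks the HisC lists were about as long as the w1118 lists, with a mean log2 ratio of covered length of 0.0066. Longer covered length in HisC could therefore hardly account for the difference even before it was tested. The difference was 0.090 and 0.066 with all peaks and still 0.084 and 0.070 with equal covered length. A background common to the HisC libraries, such as open chromatin cut without regard to the antibody, stays open. The H3K27me3 length covered by H3K4me3 was at least 1.73 times the shifted mean in HisC. As this pair is among the 15 that make up the pattern, its value restates the pattern and cannot decide for a background. The 2 pairs that went the other way show no rise in overlap at 5.5 to 6 h. A spread of marks onto each other's regions was not tested apart from such a background.

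On chromosome 4 the H3K36me3 length was lower in HisC. Shorter coverage on all chromosomes does not account for it, as the log2 ratio there was −1.22 at the closest, and the lowest of the 5 large arms at that time was −0.11. H3K4me3 peaks on chromosome 4 numbered 72 and 78 in w1118 and 106 and 115 in HisC, a log2 ratio of at least 0.56. The lowest large arm was at 0.43 and 0.55. By the outcome written beforehand, a ratio at or above the lowest large arm at both times spoke against fewer copies in HisC. That outcome had no margin for counting error. With a counting SE of 0.22 and 0.21 the ratio cannot be told apart from the lowest arm. Fewer copies of chromosome 4 in HisC therefore stay open. H3K27me3 length was lower there too, at −1.29 and −1.20, but the other marks did not share a loss of that size at both times: H3K27ac was at −0.33 and −0.34, H2BK16ac at −0.44 and −0.06, H2AK9ac at −0.74 and 0.56 and H3K4me3 at 0.30 and 0.33. A direct effect of the genotype stays open and was not tested.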
